A study of Mus musculus with 20 samples.

How the data were processed

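Tissue recombinants are grafts in which epithelium is put together with embryonic mesenchyme, which can direct what the epithelium becomes. Here mouse epithelial cells, from the seminal vesicle (SVE) or the prostate (PE) of donors aged 2 months, were combined with rat urogenital sinus mesenchyme, the embryonic tissue that induces prostate, and collected 3 months after implantation, per the labels' protocols. The labels give doxycycline in the drinking water for 3 months, which switches on the inducible vector. They put 4 libraries in each of 5 groups: SVE, PE, SVE with the construct labelled mNKX3.1, SVE with the hairpin labelled UTY_sh, and SVE with both. The labels do not say whether the m stands for mouse or for mutant, and the treatment protocol mentions both a wild type and a point mutant, so the construct is named here only as labelled. The libraries were numbered 1 to 4 within a group only to name them, so nothing pairs them across groups. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

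Poly-A RNA was made into TruSeq libraries and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.4, Cufflinks 2.0.2 and DESeq, with the mouse genome mm9. Their order, the read counter, the gene annotation and any handling of rat reads are not given in the sources used here. The deposited table holds 1 log2 value per gene and library, for 23284 genes and 20 libraries, between 0.0193 and 22.42. The values themselves show how the authors scaled them. Between log2 values of 11 and 13, the range tested, the antilogs within a library were whole multiples of what 1 read was worth, for 100% of the values tested (whole within 0.1), and that unit differed between libraries, as counts divided by a size factor per library would give. Low values were compressed towards a floor, as a variance-stabilising transformation gives: 5801 genes with a mean below 2.5 had a median of 2.27. A log2 fold change against a group near that floor is therefore understated and noisy. Whole reads could not be recovered for low genes, so no count test was run. The reads per library, from that unit, were about 20260000 to 25000000 in SVE, 14930000 to 20820000 in PE, 15470000 to 21860000 in mNKX3.1, 22520000 to 24950000 in UTY_sh and 24050000 to 29810000 in mNKX3.1+UTY_sh. Gene symbols were used as the table gives them. No coordinates are printed, because the reference genome at hand was another build than mm9. Rat reads that align to mouse genes cannot be told apart in the table, which bears most on stromal genes.

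The planned test for normalised values was limma-trend on log2(value + 1) with a minimum value of 1. The deposited values were already on a log scale, so no pseudocount was added, and genes were kept when at least 4 libraries had a value of at least 5, which left 13456. That minimum was chosen after the unit was seen and before any test was run. 1 linear model was fitted to all 20 libraries with limma 3.58.1 in R 4.3.3, with a mean per group, a trend of the variance on expression, empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison, and an adjusted p below 0.05 was called changed. All groups share 1 estimate of a gene's spread, so the standard errors of genes that varied widely in some groups only are too large for the others. The comparisons were PE, mNKX3.1, UTY_sh and mNKX3.1+UTY_sh each against SVE, mNKX3.1+UTY_sh against mNKX3.1, mNKX3.1 against PE, and the interaction, which is the hairpin's difference with the construct minus that without it. The groups, the comparisons, the test, the gene lists, the rule for named genes and most other settings tried were fixed before the data were examined.

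Named genes follow that rule. In PE against SVE, mNKX3.1 against SVE, UTY_sh against SVE and mNKX3.1+UTY_sh against mNKX3.1 they are Uty and Ehmt2, the 6 largest rises and 6 largest falls among changed genes with a mean of at least 5 and no overlap of the libraries' values, and from each list the up to 3 changed members with the smallest p, or 4 for the prostate and seminal vesicle secretory lists. In the other comparisons the 3 largest rises and falls are named. Members of those secretory lists that failed the test may also be named. Some genes that the rule selects are not reported here.

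The 26 lists were prostate secretory, seminal vesicle secretory, androgen response, endodermal and urogenital sinus regulators, Wolffian duct regulators, posterior Hox genes, luminal epithelium, basal epithelium, squamous differentiation, urothelium, fibroblast and matrix, smooth muscle, skeletal muscle, leukocyte, endothelium, kidney, adipocyte, nerve and neuroendocrine, red blood cell, proliferation, histone H3K9 and H3K27 enzymes, Y chromosome, interferon response, immediate early and heat shock, endoplasmic reticulum stress and polyamine metabolism. Some genes are in more than 1 list, among them Hoxb13, Hoxa10, Tmprss2 and Uty. Each list was compared with all other tested genes by camera in limma with a preset correlation of 0.01, adjusted over 182 tests of lists and comparisons, and again with an estimated correlation. A list score is the mean log2 value of a list's tested members in a library. Scores were compared between groups of 4 by an exact permutation test, two-sided, over 70 assignments, whose smallest p is 0.0286, with adjustment over 156 score tests.

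Comparisons that share the SVE libraries were set beside 100 simulations of unchanged groups against a shared control (20 for the overlap of calls). The simulated libraries were residuals drawn at random from all 20 libraries, not from SVE alone. The SVE libraries were also split between the comparisons in all 6 ways. The other settings fixed in advance were quantile normalisation, rescaling to the library total without the 50 most abundant genes, no filter, fits on the compared groups alone, a fold change of at least 2, and leaving out each library. A smaller pseudocount and the tests for counts, also fixed in advance, had no use on log2 values and were not run. Settings added after seeing the data were a minimum value of 7 and robust empirical Bayes. A fit without 3 libraries of SVE type with Pbsn above 0.0625 of the PE mean, and for named genes a fit on PE and mNKX3.1 alone, were also added then. To ask whether a library resembled a weighted sum of 2 others, non-negative weights were fitted with scipy 1.17.1 and numpy 2.4.6 on 310 of the 620 genes above a log2 value of 11 in all libraries, and the squared residuals were divided by counting noise on the other 310. Simulated sums of 2 PE libraries in equal parts, with the PE values taken as true means, were fitted in the same way. A second set had added noise per gene, of a size chosen freely. Tables were handled with python 3.11.15 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9.

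The test was run on simulated data with the real genes' means and spreads. In simulated PE against SVE over 13456 genes, 58% of the genes changed by a log2 of 0.5 were recovered, 86% of those changed by 1 and 98% of those changed by 2, with 16 false calls among 186. In simulated UTY_sh against SVE the shares were 72%, 88% and 94%, with 14 false calls among 190. In simulated mNKX3.1 against PE they were 52%, 88% and 98%, with 17 false calls among 186. The other simulated comparisons gave 9 false calls among 194 (mNKX3.1 against SVE), 11 among 179 (mNKX3.1+UTY_sh against mNKX3.1) and 4 among 178 (mNKX3.1+UTY_sh against SVE), so the share of false calls was above the nominal 5% in some draws and below it in others.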

Results

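Poly-A RNA was measured in 20 libraries from tissue recombinants of mouse epithelium and rat urogenital sinus mesenchyme, 4 libraries in each of 5 groups. SVE and PE are the grafts of unmodified seminal vesicle and prostate epithelium. The libraries labelled mNKX3.1, UTY_sh and mNKX3.1+UTY_sh are grafts of seminal vesicle epithelium with a construct, a hairpin or both. UTY is the Y-linked relative of the histone demethylase KDM6A, and EHMT2 (G9a) is a histone methyltransferase. The series' title places these proteins in a network that acts in prostate differentiation. The mean depth was about 23480000 ± 2230000 reads in SVE (SD, n = 4), 18570000 ± 2730000 in PE, 19230000 ± 2810000 in mNKX3.1, 23780000 ± 1010000 in UTY_sh and 26060000 ± 2590000 in mNKX3.1+UTY_sh. The 50 most abundant genes took 63.8%, 36.7%, 36.7%, 64.6% and 63.8% of the reads in these groups. The most abundant gene was Svs2, which encodes a seminal vesicle secretory protein, in every SVE, UTY_sh and mNKX3.1+UTY_sh library, and 9530053A07Rik in every PE and mNKX3.1 library. PE and mNKX3.1 were thus sequenced less deeply, and spread their reads over more genes. Values are log2 throughout, and folds of genes near the floor of about 2.27 are understated.

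Uty and Ehmt2 were examined first, in every library. Uty averaged 9.29 ± 0.21 in SVE (SD, n = 4), 10.24 ± 0.14 in PE, 10.23 ± 0.11 in mNKX3.1, 9.22 ± 0.23 in UTY_sh and 9.15 ± 0.09 in mNKX3.1+UTY_sh. The libraries labelled UTY_sh differed from SVE by -0.07, with a 95% interval from -0.301 to 0.163, and those labelled mNKX3.1+UTY_sh by -0.14, with an interval from -0.368 to 0.0958, so neither passed the test. Ehmt2 averaged between 11.28 and 11.37 in the 5 groups and passed in no comparison. Neither hairpin group had a fall in Uty from SVE that passed the test, so the groups are named below only as labelled.

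**Figure D1:**
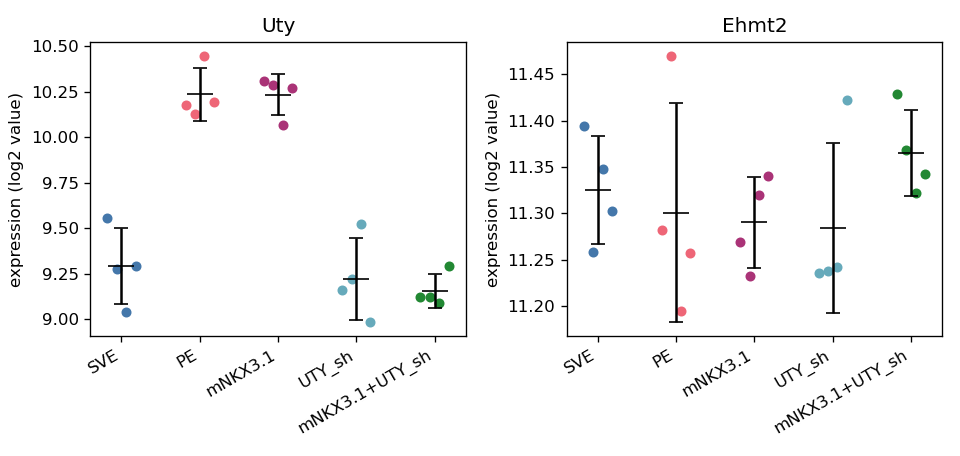
Log2 values of Uty and Ehmt2 in each of the 20 libraries by group, with points for libraries and bars for mean ± SD (n = 4). Uty averaged 10.24 in PE and 10.23 in mNKX3.1, and 9.29, 9.22 and 9.15 in SVE, UTY_sh and mNKX3.1+UTY_sh.

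PE and SVE were compared to see what separates prostate from seminal vesicle epithelium under the same mesenchyme. In PE the prostate secretory genes rose: of 19 measured, 17 were higher and 1 lower, and the same numbers passed when adjusted over the list alone. Msmb, which encodes the prostate secretory protein beta-microseminoprotein, rose by 9.89 (SE 0.76, adjusted p = 3.76e-09), from 4.64 ± 1.64 to 14.53 ± 0.56 (SD, n = 4), and the beta-defensin gene Defb50 rose by 8.77 (SE 0.85). Apof, an apolipoprotein gene, rose by 2.57, and Folh1, the gene of prostate-specific membrane antigen, fell by 2.20. Spink5, with a difference of 2.89 (SE 2.00), did not pass. All 14 seminal vesicle secretory genes fell, 14 also when adjusted over the list alone: Sva fell by 10.88 (SE 0.37, adjusted p = 6.05e-14), from 17.59 to 6.71, and the changes in Svs3a, Svs3b and Ceacam10 were -10.26, -10.40 and -10.38. Also among the 6 largest rises were Wfdc3, a whey acidic protein family gene, at 9.01 (SE 0.52), 5430419D17Rik at 8.98 (SE 1.04), and the prostate list's 9530002B09Rik at 7.97 and 9530053A07Rik at 7.90. Among the falls, Dnase2b, a gene of the DNase II family, fell by 10.44 (SE 0.31), and the changes were -10.58 for Svs6 and -10.35 for Svs1. Svs3a and Svs3b, and likewise Sbp and Sbpl, are close copies, so how reads were split between them is uncertain.

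Regulators differed as well. Of 8 endodermal and urogenital sinus regulators, 4 were higher in PE and 2 lower, the same when adjusted over the list alone. Foxa1, a pioneer factor of prostate epithelium, rose by 2.46 (SE 0.23, adjusted p = 5.63e-08) and Ehf, an epithelial ETS factor, by 1.22, while Gata2 fell by 1.74. Of 8 Wolffian duct regulators, 2 were higher and 4 lower (2 and 5 when adjusted over the list alone). Pax2, a paired-box factor of the Wolffian duct, from which the seminal vesicle develops, fell by 5.21 (SE 0.28, adjusted p = 3.07e-11), and Pax8 fell by 1.93, whereas Hoxa10 rose by 1.48. Neither list differed from the other genes by camera (adjusted p = 0.756 and 0.372, and 0.998 and 0.987 with an estimated correlation).

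Other cell types and cell states moved with the same groups. All 10 smooth muscle genes were lower in PE, 10 also when adjusted over the list alone. Lmod1, an actin nucleator of smooth muscle, fell by 1.88 (SE 0.12, adjusted p = 2.28e-10), Des by 1.35 and Smtn by 1.09. Of 13 endoplasmic reticulum stress genes, 11 were higher by limma (12, and 1 lower, when adjusted over the list alone). The chaperone gene Pdia4 rose by 1.85 (SE 0.17), Dnajc3 by 1.46 and Sdf2l1 by 1.39. All 5 nerve and neuroendocrine genes were higher, 5 also when adjusted over the list alone, with Tubb3 up by 4.39 and Syp by 1.94. The 6 adipocyte genes were higher too, 6 also when adjusted over the list alone, among them Cidec at 3.04 (SE 0.73), Adipoq at 2.32 and Retn at 1.92, and camera gave adjusted p = 0.158 (0.998 with an estimated correlation). Rat and mouse reads cannot be told apart in these genes.

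Over all 13456 genes limma called 8362 between PE and SVE, 4275 higher and 4087 lower (3514 and 4798 after rescaling), of which 2120 changed at least 2-fold. By camera 5 of 26 lists were called: seminal vesicle secretory down (adjusted p = 3.66e-11, and adjusted p = 0.127 with an estimated correlation), and prostate secretory up (0.00165), smooth muscle down (1.49e-04), endoplasmic reticulum stress up (4.07e-04) and nerve and neuroendocrine up (0.0408), each of these 4 at adjusted p = 0.987 with an estimated correlation. The score tests reached their smallest p of 0.0286 (exact permutation test, two-sided; adjusted p = 0.111) for the prostate and seminal vesicle secretory lists, with all 4 PE libraries on one side of all 4 SVE libraries. Prostate genes varied widely within SVE, where the prostate secretory score had an SD of 1.95 (n = 4) and replicate 1 held Pbsn, the androgen-dependent probasin gene, at 23.3% of the PE mean. Without that library, UTY_sh replicate 3 and mNKX3.1+UTY_sh replicate 4, chosen after Pbsn was seen, limma called 8290 genes.

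**Figure D2:**
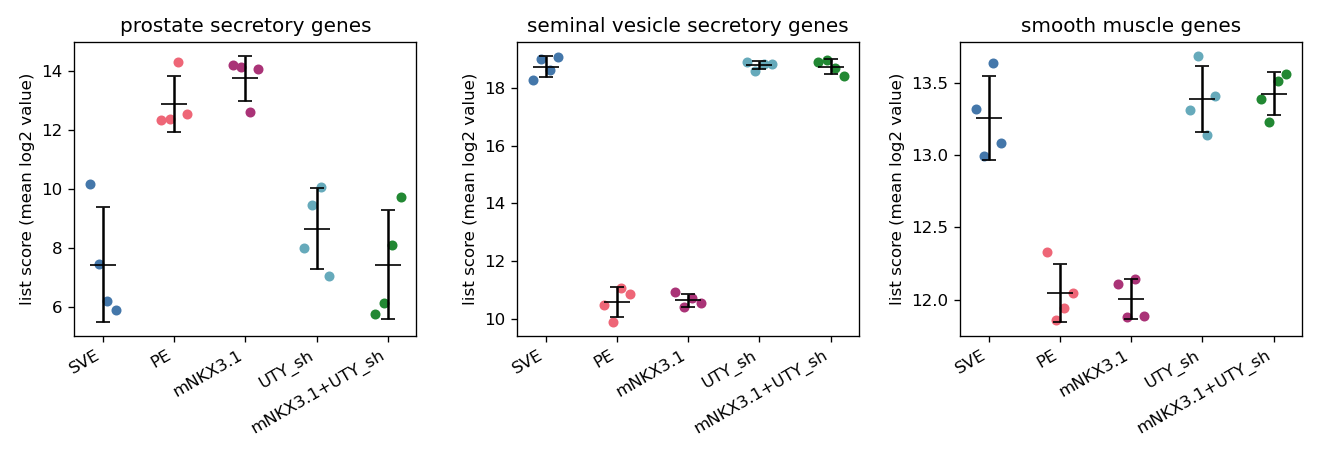
List scores (mean log2 value of the list's tested genes) per library by group for prostate secretory, seminal vesicle secretory and smooth muscle genes, with bars for mean ± SD (n = 4). The prostate secretory score averaged 12.88 in PE and 13.74 in mNKX3.1, and 7.41, 8.63 and 7.43 in SVE, UTY_sh and mNKX3.1+UTY_sh.

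The libraries labelled mNKX3.1 were compared with SVE to see what the construct changes. Seminal vesicle genes fell and prostate genes rose, by sizes near those in PE. Of 19 prostate secretory genes, 18 were higher and 1 lower, and of 14 seminal vesicle secretory genes, 13 were lower, with the same numbers when adjusted over the list alone. Sbp and Sbpl, which encode spermine-binding proteins of the prostate, rose by 13.24 (SE 2.43, adjusted p = 1.24e-04) and 11.85 (SE 2.35), 5430419D17Rik by 10.69, Msmb by 10.11 (SE 0.76), Wfdc3 by 9.34 and Defb50 by 8.91. Sva fell by 11.34 (SE 0.37, adjusted p = 3.27e-14), and the changes were -11.28 for Svs6, -10.94 for Ceacam10, -10.91 for Svs3b and -10.88 for Svs3a and Dnase2b. Among the regulators Pax2 fell by 5.30 (SE 0.28), Pax8 by 2.24 and Gata2 by 1.83, and Foxa1 rose by 2.54 (SE 0.23) and Ehf by 1.18. Uty rose by 0.94 (SE 0.11, adjusted p = 7.46e-07).

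All 10 smooth muscle genes fell here too, and 11 of 13 endoplasmic reticulum stress genes rose and 1 fell, the same when adjusted over each list alone. Lmod1 fell by 1.97, Des by 1.39 and Smtn by 1.15, and Pdia4 rose by 1.79, Dnajc3 by 1.42 and Sdf2l1 by 1.33. The 5 nerve and neuroendocrine genes and 6 adipocyte genes were all higher, with the same numbers when adjusted over the list alone, Tubb3 by 4.59, Adipoq by 2.63 and Cidec by 3.22. Limma called 8385 genes, 4263 higher and 4122 lower (3619 and 4716 after rescaling), 2249 of them at least 2-fold changed. Camera called 5 lists: seminal vesicle secretory (adjusted p = 5.62e-11, and adjusted p = 0.127 with an estimated correlation), prostate secretory (4.19e-04), smooth muscle (1.33e-04), endoplasmic reticulum stress (4.19e-04) and nerve and neuroendocrine (0.0449), the latter 4 at adjusted p = 0.987 with an estimated correlation. The adipocyte list gave adjusted p = 0.0994 (0.998 with an estimated correlation). Replicate 3 of mNKX3.1 stood apart for Sbp, at 8.46 against a group mean of 15.93 ± 4.98 (SD, n = 4), and without the 3 libraries rich in Pbsn limma called 8312 genes.

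The 2 comparisons with SVE were then set against each other. Of the genes called in PE against SVE, 93.8% were called the same way in mNKX3.1 against SVE: 3971 were higher in both and 3871 lower in both, with 0 called in opposite directions by limma, against 1354 and 1252 for independent lists. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.988, with a slope of 1.02 and the same sign for 95.8% of genes. Unchanged groups simulated against a shared control, from residuals of all 20 libraries, gave a mean correlation of 0.531 and at most 0.891. They shared 67.3% of signs. Their overlap was at most 0 calls in 20 simulations, which unchanged groups with few calls would give anyway. The correlation that the SVE libraries alone would bring was not simulated. With the SVE libraries split between the comparisons the correlation was 0.940 to 0.969 and the overlap 4359 to 5006 genes. The covariance was 1.15 against 0.0261 simulated, a difference of 1.12.

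**Figure D3:**
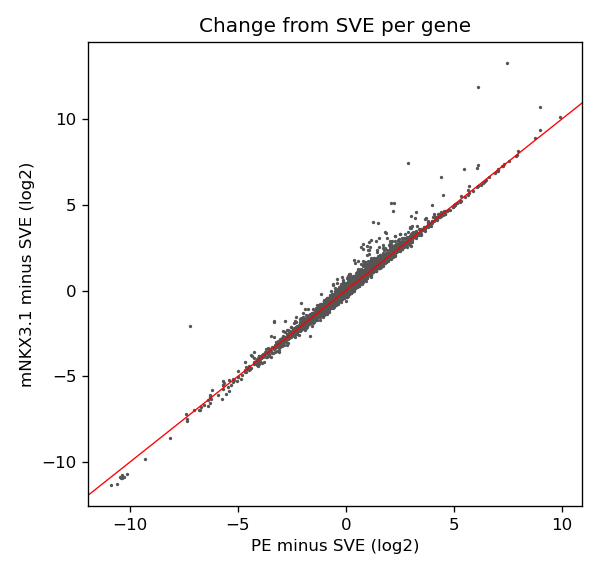
Log2 fold change against SVE for each of 13456 genes, PE on the horizontal axis and mNKX3.1 on the vertical axis, with a red line of equality. The points lie along the line, with a correlation of 0.988 across genes and a slope of 1.02.

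What still differed between mNKX3.1 and PE was tested directly. Limma called 0 of 13456 genes, with 65 genes (0.483%) at an unadjusted p below 0.05. Unchanged, independent groups would give about 5% on average, so the 2 group means lay nearer than the shared spread would give. Genes vary together and all groups share that spread, and the cause was not tested. Ehmt2 differed by -0.01 (SE 0.06). Uty averaged 10.23 against 10.24. Sbp, at 15.93 ± 4.98 against 10.12 ± 6.26 (SD, n = 4), had a difference with an SE of 2.43, and Sbpl differed by 5.74, Spink5 by 4.51 and the seminal vesicle list's Spink3 by 5.15, each at adjusted p = 0.9999; Sbp was high in PE replicate 3 alone among the PE libraries, at 400% of the PE mean. Camera placed the interferon response list up (adjusted p = 0.00387) and the seminal vesicle secretory list down (0.00864), and the prostate secretory list up (0.0373). With an estimated correlation these were at adjusted p = 0.987, 0.987 and 0.998. In limma 0 members of these lists passed, over all genes or when adjusted over the list alone, and at an unadjusted p below 0.05 these were 0, 1 and 3 genes, all higher. For the seminal vesicle list the median was -0.433 and the mean 0.0722, so they differ in sign, and for the prostate list the call was lost after rescaling (adjusted p = 0.152). In simulated data of this design 98% of changes of 2 were recovered and 52% of changes of 0.5 (log2), so many small differences were not detectable. The simulation drew independent libraries with 1 spread per gene in all groups, so these rates may not hold for mNKX3.1 against PE. Each mNKX3.1 library also lay nearer to a weighted sum of 2 PE libraries than the reverse. On 310 genes outside the fit, the squared residuals were 2.38, 4.19, 2.44 and 1.62 times the counting noise for replicates 1 to 4. PE libraries as sums of 2 mNKX3.1 libraries gave 6.04 to 10.3, and simulated sums with counting noise alone gave 0.544 to 0.878. That simulated range lies below 1 by construction, because the PE values were taken as true means.

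**Figure D4:**
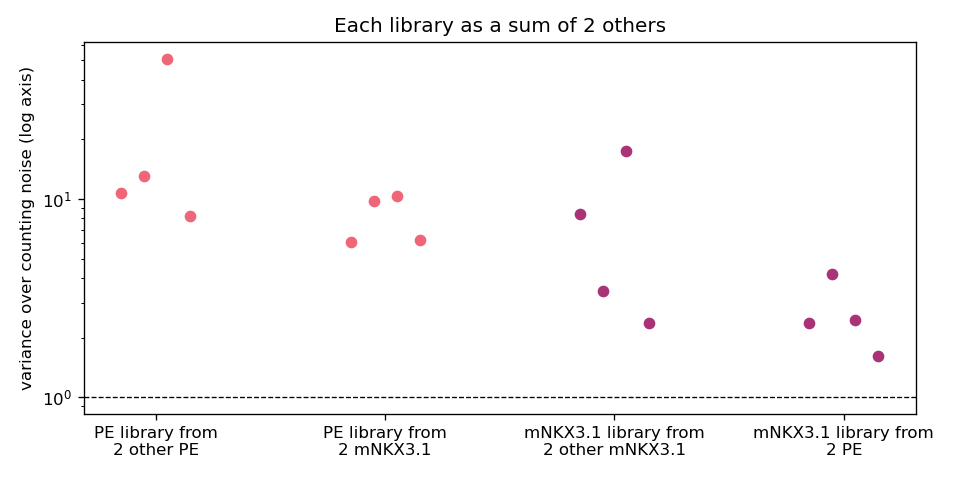
Squared residual over counting noise (log axis, dashed line at 1) for each PE or mNKX3.1 library fitted as a weighted sum of 2 others, on 310 genes outside the fit, with 1 point per library. Fitted from 2 PE libraries, mNKX3.1 libraries gave 1.62 to 4.19, and fitted from 2 others of their own group they gave 2.37 to 17.5. PE libraries gave 8.22 to 50.7 from 2 other PE libraries and 6.04 to 10.3 from 2 mNKX3.1 libraries. Pairs from the own group were chosen from fewer libraries than pairs from the other group.

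The libraries labelled UTY_sh were compared with SVE for what the hairpin changes alone. Limma called 0 of 13456 genes, with 316 (2.35%) at an unadjusted p below 0.05. The prostate secretory genes lay higher without any member passing, over all genes or when adjusted over the list alone: Pbsn differed by 2.16 (SE 1.96), Tgm4 by 2.09 and Sbp by 4.61 (SE 2.43), with 0 members at an unadjusted p below 0.05 in limma, and the list's camera test gave adjusted p = 0.0102 (adjusted p = 0.987 with an estimated correlation). The SE of Sbp is shared with PE and mNKX3.1, where Sbp varied widely. Its values were 3.48 to 9.72 in UTY_sh and 1.84 to 3.45, near the floor, in SVE. A fit on the compared groups alone also called 0 genes. The adipocyte list was also placed up (adjusted p = 0.00219, and adjusted p = 0.987 with an estimated correlation), as was smooth muscle (0.0265, and adjusted p = 0.998 with an estimated correlation). The interferon response list was placed down (0.0493, and adjusted p = 0.998 with an estimated correlation). In these 3 lists, too, 0 members passed in limma, over all genes or when adjusted over the list alone, and 1, 0 and 0 had an unadjusted p below 0.05. Their smooth muscle and seminal vesicle secretory scores were 13.39 and 18.78, against 13.26 and 18.74 in SVE.

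The libraries labelled mNKX3.1+UTY_sh were compared with those labelled mNKX3.1 for what the hairpin changes beside the construct. The seminal vesicle genes were higher, with Sva up by 11.23 (SE 0.37, adjusted p = 3.47e-14), Svs6 by 11.22, Svs3a by 10.95, Svs1 by 10.91, and Ceacam10 and Svs3b by 10.90, and 13 of 14 rose. Of 19 prostate secretory genes 18 fell and 1 rose: the changes were -12.84 for Sbp (SE 2.43), -11.44 for Sbpl, -10.84 for Msmb (SE 0.76, adjusted p = 1.04e-09) and -9.55 for Defb50, while Folh1 rose by 2.43. Uty fell by 1.08 (SE 0.11, adjusted p = 1.37e-07) and Foxa1 by 2.56, whereas Pax2 rose by 5.36 and Gata2 by 1.86. All 10 smooth muscle genes rose, Lmod1 by 2.18, and 12 of 13 endoplasmic reticulum stress genes fell and 1 rose. The counts were the same when adjusted over each list alone. Of the genes called in mNKX3.1 against SVE, 7668 were called in the opposite direction here and 0 in the same direction by limma, which the shared mNKX3.1 libraries favour.

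Limma called 8580 genes in this comparison, 4223 higher and 4357 lower (4795 and 3752 after rescaling), 2331 at least 2-fold, and 8407 without the 3 libraries rich in Pbsn. Camera called seminal vesicle secretory (adjusted p = 9.63e-11, and adjusted p = 0.127 with an estimated correlation), smooth muscle (6.68e-05), endoplasmic reticulum stress (4.07e-04) and prostate secretory (5.53e-04), these 3 at adjusted p = 0.987 with an estimated correlation. The 5 nerve and neuroendocrine genes and 6 adipocyte genes all fell, also when adjusted over the list alone, with Tubb3 at -4.83 and Adipoq at -3.07, and camera gave adjusted p = 0.0579 and 0.0785 (0.987 and 0.998 with an estimated correlation, and 0.0352 and 0.0401, so called, after rescaling). Uty was lower than in mNKX3.1 and near its level in SVE, so the difference from mNKX3.1 is no check of the hairpin.

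Both constructs together were also compared with none. Between mNKX3.1+UTY_sh and SVE limma called 0 genes, with 557 (4.14%) at an unadjusted p below 0.05 and a smallest adjusted p of 0.211. Pbsn differed by 0.13 (SE 1.96) and Svs6 by -0.06 (SE 0.40). Camera placed smooth muscle up (adjusted p = 0.00915) and basal epithelium up (0.0352), both at adjusted p = 0.987 with an estimated correlation. In these lists 0 members passed in limma, over all genes or when adjusted over the list alone, and 0 and 1 had an unadjusted p below 0.05.

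Whether the hairpin's difference depended on the construct was tested as an interaction. Limma called 6467 genes, 3234 higher and 3233 lower (3729 and 2791 after rescaling), 2175 at least 2-fold, and 6186 without the 3 libraries rich in Pbsn. The highest values were Sva at 11.26 (SE 0.52, adjusted p = 1.50e-11), Svs6 at 11.24 and Ceacam10 at 10.91, and the lowest Sbp at -17.45 (SE 3.44), Sbpl at -14.93 and 5430419D17Rik at -12.75. Of the lists, 13 of 14 seminal vesicle secretory genes were higher (adjusted p = 2.38e-12, and adjusted p = 0.127 with an estimated correlation), 10 of 10 smooth muscle genes higher (1.14e-04), 18 of 19 prostate secretory genes lower and 1 higher (1.76e-04), 11 of 13 endoplasmic reticulum stress genes lower (3.74e-04) and 6 of 6 adipocyte genes lower (0.0282), these 4 at adjusted p = 0.987 with an estimated correlation. The 5 nerve and neuroendocrine genes were lower too (adjusted p = 0.0553, and adjusted p = 0.987 with an estimated correlation), a list called only after rescaling (0.0352). Adjusted over the list alone the counts were the same, with 1 endoplasmic reticulum stress gene also higher. Across genes, which are not independent replicates, the hairpin's differences without and with the construct had a correlation of -0.145 (Spearman 0.0795). Since no fall in Uty from SVE passed the test in either hairpin group, the interaction describes the libraries only as labelled.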

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

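All tests of explanations in this part were chosen only after the results were seen. Each library labelled mNKX3.1 lay near a weighted sum of 2 PE libraries, at 2.38, 4.19, 2.44 and 1.62 times counting noise. For replicate 1, for example, the weights were 0.46 and 0.532 on PE replicates 1 and 3. All these ratios lay above the 0.544 to 0.878 of 6 simulated sums with counting noise alone. They lay below the 27.5 to 41.3 of sums with added gene noise. The simulations took the PE values as true means, which puts the first range below 1, and the amount of gene noise was chosen freely. These 2 ranges therefore set no bounds for real sums. Columns averaged after counting are argued against, since 100% of mNKX3.1 values tested lay on the grid of whole reads and at most 26.03% did in computed averages. RNA or reads of PE libraries in the mNKX3.1 libraries could give the levels of 59 genes high in PE replicate 3 and outside the fit. Their levels were 55.6%, 53.6%, 8.29% and 46.3% of that library against 57.4%, 57.1%, 8.47% and 46.9% predicted, a largest gap of 3.5 points. Sums with counting noise alone might lie nearer, but their gap was not simulated for these genes. Grafts that vary from each other as the PE grafts do cannot be told apart: 1 of 70 assignments of the 8 libraries was as low (a share of 0.0143), but that test was taken from the same residuals and in the direction already seen, and the next mean log2 ratio was near, at 1.56 against 1.33; SVE grafts turned into prostate tissue by the construct are not weighed here, and grafts that hold different shares of the same tissues could also look like sums. Only PE replicate 3 had such genes, and Sbp in mNKX3.1 replicate 3 was 8.46 against 6.52 predicted. From their own group mNKX3.1 replicates 2 and 4 gave 3.42 and 2.37. Both were fitted from PE replicates 2 and 3, with weights of 0.442 and 0.536 and of 0.558 and 0.425, so such sums would also resemble each other. As sums of any 2 other libraries, a wider choice, mNKX3.1 replicates 1 to 4 gave 2.38, 2.43, 2.44 and 1.57. By that choice UTY_sh gave 2.5 to 4.31, mNKX3.1+UTY_sh 2.74 to 7.65, SVE 6.24 to 10.1 and PE 6.04 to 10.3. Some libraries of the hairpin groups, such as UTY_sh replicate 1 at 2.5, thus lay near the mNKX3.1 libraries.

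Uty was only slightly lower in the libraries labelled UTY_sh or mNKX3.1+UTY_sh than in SVE, and neither difference passed the test. Too weak a measurement to show a halving of Uty is argued against for the graft as a whole, since the 95% interval of UTY_sh minus SVE ended at -0.301. Rat and mouse reads cannot be told apart there, so this bound does not cover the epithelium alone. Libraries or a whole group under a wrong label, and an action of the hairpin on the protein alone, are not weighed here.

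Prostate genes varied together among the SVE, UTY_sh and mNKX3.1+UTY_sh libraries, and Pbsn, chosen after its values were seen, reached 23.3%, 12.5% and 14.9% of the PE mean in SVE replicate 1, UTY_sh replicate 3 and mNKX3.1+UTY_sh replicate 4. Tissue like the PE grafts is argued against, since Msmb, Defb50 and Wfdc3 reached at most 1.62% there. Prostate tissue of another kind cannot be told apart, because Tgm4 and Pbsn stood at ratios of 1.06 to 1.21, which any such tissue could give. Hoxb13 (25.2%, 12.6% and 15.5%), 9530053A07Rik (21.3%, 9.7% and 15.6%) and 9530002B09Rik (18.8%, 10.3% and 12.1%) rose to similar shares in these libraries. Sbp and 5430419D17Rik reached at most 0.247% there. Apof did not follow Pbsn, with 18.1% also in SVE replicate 4, where Pbsn was at 0.0376%. RNA or reads of SVE replicate 1 in the other libraries also stays open: the weights predicted 8.1% and 15.7% for Pbsn in UTY_sh replicate 3 and mNKX3.1+UTY_sh replicate 4, and the highest ratio of measured to predicted was 1.54. UTY_sh replicate 2, with Pbsn at 6.23% of the PE mean, lay just below the cut of 0.0625 of that mean. It therefore stayed in the fits without the libraries rich in Pbsn. No biological explanation was tested for this pattern of prostate genes.

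The remaining values concern single libraries far from the other 3 of their group, and differences between groups. Of 580 sets of 4 values tested, 50 had a library apart (8.62%), where chance gives about 5%, or 1 in 20: 9 in SVE, 11 in PE, 16 in mNKX3.1, 4 in UTY_sh and 10 in mNKX3.1+UTY_sh. In SVE, replicate 1 was highest for Cd24a (13.75), Foxa1 (10.24), Itga6 (9.07) and Sat1 (9.58) and lowest for Hoxd9 (9.78). SVE replicate 3 was highest for Col1a2 (11.92), Folh1 (5.86) and the fibroblast and matrix score (10.999), and lowest for Abcc4 (8.62). In PE, replicate 3 was highest for Fabp4 (10.12), Sbpl (17.36), Upk1a (12.24), the adipocyte score (8.50) and the prostate secretory score (14.30). PE replicate 3 was lowest for Syp (5.47), Tubb3 (4.84), the endothelium score (7.54) and the nerve and neuroendocrine score (5.44). PE replicate 1 was lowest for Cdyl (7.36), and PE replicate 2 for Kdm5d (9.12).

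In mNKX3.1, replicate 3 was lowest for 5430419D17Rik (10.71), Adipoq (7.05), Fabp4 (8.86), Sbp (8.46), Sbpl (6.84), Upk1a (10.53) and Uty (10.07). Its scores were lowest for the adipocyte (7.43), interferon response (6.08) and prostate secretory lists (12.61). The same library was highest for Kdr (7.95), Sdf2l1 (12.0025) and Upk1b (10.61). Replicate 1 of mNKX3.1 was lowest for Cd74 (10.03) and the red blood cell score (7.29) and highest for the posterior Hox genes score (7.50). In UTY_sh, replicate 4 was highest for Ehmt2 (11.42), replicate 3 lowest for Rrm2 (6.94) and highest for the endoplasmic reticulum stress score (11.93), and replicate 1 lowest for Myh1 (2.24). In mNKX3.1+UTY_sh, replicate 4 was highest for Creld2 (10.73), Ddx3y (10.62), Defb50 (7.85), Msmb (6.04), Sat1 (9.41) and Uty (9.29), and lowest for Gata2 (13.93) and Kdm6b (10.63). Replicate 2 of that group had the lowest fibroblast and matrix score (10.58) and squamous differentiation score (4.50).

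The hairpin's difference with the construct differed from that without it for 6467 genes by limma's interaction test. It was -1.01 for Uty. It was 11.26 for Sva, 11.24 for Svs6 and 10.91 for Ceacam10. It was -17.45 for Sbp, -14.93 for Sbpl and -12.75 for 5430419D17Rik. The mean over the list was -7.54 for prostate secretory, 8.05 for seminal vesicle secretory, 1.29 for smooth muscle, -3.60 for adipocyte and -0.976 for endoplasmic reticulum stress genes.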

How the results depend on the processing

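The minimum value of 7, robust empirical Bayes, the fit without libraries rich in Pbsn and the fit of named genes on PE and mNKX3.1 alone were tests chosen only after the results were seen. Every count of genes above 0 stayed within 1.5 times its main value, except with a fold change of at least 2, which by construction left 2120 genes in PE against SVE, 2249 in mNKX3.1 against SVE, 2331 in mNKX3.1+UTY_sh against mNKX3.1 and 2175 in the interaction. With each library left out, limma called 7776 to 8359, 7800 to 8330, 7980 to 8304 and 5990 to 6668 genes in these comparisons. In UTY_sh against SVE, mNKX3.1+UTY_sh against SVE and mNKX3.1 against PE, each alternative run gave 0 genes, beside 316, 557 and 65 at an unadjusted p below 0.05 in limma. With an estimated correlation between genes, camera called 0 lists in each of the 7 comparisons, against 5, 5, 4, 4, 2, 3 and 5 with the preset one; the cause was not tested. The correlation of both comparisons with SVE was 0.952 on average with the SVE libraries split, which removes the shared controls, and 0.966 without PE replicate 3 to 0.991 without mNKX3.1 replicate 2, with 0.975 without mNKX3.1 replicate 3; the cause of that range was not tested. Of 3788 values of named genes under alternatives, 38 lost their call, among them values of Kdm5d, Atf3, Ifit2 and Ier2, and 0 gained one or reversed; Uty and Ehmt2 kept their direction where called and their side of the threshold in all settings run. Quantile normalisation and rescaling moved the median of all genes by less than 0.1, with -0.055 the largest median after rescaling, but the share of calls that were higher went from 51.1% to 42.3% in PE against SVE, from 50.8% to 43.4% in mNKX3.1 against SVE, from 49.2% to 56.1% in mNKX3.1+UTY_sh against mNKX3.1 and from 50% to 57.2% in the interaction after rescaling, so which direction holds most calls depends on the scaling. After rescaling camera also called nerve and neuroendocrine (adjusted p = 0.0352) and adipocyte genes (0.0401) in mNKX3.1+UTY_sh against mNKX3.1 and nerve and neuroendocrine genes in the interaction (0.0352), and no longer called prostate secretory genes in mNKX3.1 against PE (0.152). The planned filter and pseudocount assumed values on a linear scale: the filter was replaced by a value of at least 5, and a smaller pseudocount, other size factors and the count tests were not run. No paired analysis was possible because the replicate numbers only name the libraries. PE and mNKX3.1 had fewer reads per library on average than the other groups. The 50 most abundant genes took only 36.7% of them, against 63.8% to 64.6% in the others. On the scale of the deposited values 1 read was worth 0.717 to 1.05 in PE and mNKX3.1 and 0.809 to 1.30 in the others. Fewer reads in total therefore did not mean fewer reads for their low genes.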

Other observations

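The tests over other splits of the libraries and without the libraries rich in Pbsn in this part were chosen only after the results were seen. In PE against SVE, camera called none of the gene groups not described above, and most of them changed only in part. Of 12 luminal epithelium genes 8 were higher and 3 lower, with the adhesion gene Epcam at 1.73 (SE 0.16), Cd24a at 1.66 and Cdh1, the E-cadherin gene, at 0.71. Of 11 basal epithelium genes 3 were higher and 5 lower (3 and 6 when adjusted over the list alone), with Trp63, the basal cell transcription factor, at -1.14, Itgb4 at -1.01 and Itga6 at 1.97. Of 10 posterior Hox genes 4 were higher and 3 lower (4 and 4 when adjusted over the list alone), with Hoxd9 at -3.55 (SE 0.20), Hoxa9 at 2.09 and Hoxa10 at 1.48. Of 5 urothelium genes 2 rose and 2 fell, Upk1a by 5.68 and Upk1b by 0.69 against Upk2 at -2.45, and 0 of 2 squamous genes passed in limma, with 0 at an unadjusted p below 0.05. Of 17 androgen response genes 5 were higher and 8 lower (6 and 8 when adjusted over the list alone), with the fatty acid elongase gene Elovl5 at -0.99, Herc3 at -1.59 and Abcc4 at 1.14. Of 6 polyamine genes 3 were higher and 1 lower, Sat1, which encodes spermidine acetyltransferase, by 1.13, Sms, the spermine synthase gene, by 1.37 and Azin1 by 0.32. Where no second count is given, adjustment over the list alone gave the same one. Camera gave adjusted p = 0.344, 0.745, 0.998, 0.998, 0.998, 0.954 and 0.577 for these lists in the order luminal, basal, posterior Hox, urothelium, squamous, androgen response and polyamine, each at adjusted p = 0.998 with an estimated correlation.

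Among other cell types, the antigen presentation genes H2-Aa, Cd74 and H2-Ab1 fell by 0.94, 0.93 and 1.07 in PE against SVE, and of 12 leukocyte genes 1 was higher and 4 lower. Of 12 fibroblast and matrix genes 6 were lower, with Thy1 at -1.34, Col1a1 at -0.68 and Fn1 at -0.57, and of 8 endothelium genes 1 was higher and 4 lower, with Kdr, a VEGF receptor gene, at -0.96, Tie1 at -0.54 and Esam at -0.49. Of 3 skeletal muscle genes 1 was higher and 2 lower, with Myh1 at 1.90, Acta1 at -1.32 and Ckm at -0.67, Lrp2 of the kidney list fell by 1.97, and 0 of 1 red blood cell gene passed in limma, with 0 at an unadjusted p below 0.05. Of 16 histone enzyme genes 4 were higher and 5 lower, with Cdyl at -1.39, Uty at 0.95 and Kdm6b at -0.57, and of 4 Y chromosome genes 3 were higher, Uty and Ddx3y by 0.95 and 0.76 and Kdm5d by 0.19, a call lost without SVE replicate 1 (limma adjusted p = 0.108) or PE replicate 1, 3 or 4 (0.0845, 0.0956 and 0.082), after rescaling (0.165), with no filter (0.055), in a fit on the compared groups alone (0.119) and without the libraries rich in Pbsn (0.13). Of 9 proliferation genes 2 were higher and 2 lower, with Top2a at 1.38 and Rrm2 at -0.72, of 16 interferon response genes 2 were higher and 5 lower (2 and 4 when adjusted over the list alone), with Usp18 at -2.27 and Mx1 at 1.42, and of 11 immediate early and heat shock genes 2 were higher (1 when adjusted over the list alone), with Hsph1 at 1.74 and Atf3 at 0.49, whose call was lost without SVE replicate 2 (adjusted p = 0.0508) or PE replicate 2 or 4 (0.0905 and 0.0623) and in a fit on the compared groups alone (0.067). The other counts were the same when adjusted over the list alone. Camera gave adjusted p of 0.344 to 0.987 for these 11 lists, and 0.987 or 0.998 with an estimated correlation.

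The mean, the median and the direction of the camera test differed in sign for some lists. In PE against SVE this held for 4 lists: androgen response, posterior Hox, basal epithelium and leukocyte, with medians of -0.238, -0.286, -0.388 and 0.371 and means of 0.495, 0.555, 0.0751 and 0.121. In mNKX3.1 against SVE it held for those 4 and for skeletal muscle, proliferation and immediate early genes. In UTY_sh against SVE it held for 9 lists: endodermal regulators, posterior Hox, luminal epithelium, urothelium, skeletal muscle, leukocyte, nerve, proliferation and immediate early. In mNKX3.1+UTY_sh against mNKX3.1 it held for androgen response, posterior Hox, skeletal muscle, leukocyte and immediate early genes, and in the interaction for these 5 and urothelium. In mNKX3.1+UTY_sh against SVE it held for both secretory lists, androgen response, endodermal regulators, urothelium, skeletal muscle and immediate early genes. In mNKX3.1 against PE it held for seminal vesicle secretory, urothelium, skeletal muscle, red blood cell and polyamine genes.

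Other splits of the same libraries into groups of the same sizes were counted. In PE against SVE 1 of 35 splits, the real one, gave as many genes as the 8362 called, with 3027 in the next. No smaller share can come from 35 splits, and the test was chosen after the results were seen, so it cannot exclude chance. In mNKX3.1 against SVE and in mNKX3.1+UTY_sh against mNKX3.1, 1 of 35 splits gave as many as 8385 and 8580. The other splits gave at most 0 genes by limma, and the same limit holds. Splits that mix unlike groups also put their difference into the spread, which lowers the calls. In UTY_sh against SVE, mNKX3.1+UTY_sh against SVE and mNKX3.1 against PE, 0 genes were called by limma. There 35 of 35 splits gave as many, which any split must do when the real count is 0, so that share tests nothing. Other splits gave up to 161, 364 and 983 genes. Splits that call more genes than the labels can point to a structure among the libraries, but no such maximum was computed for libraries without one. In the interaction, with mNKX3.1 and mNKX3.1+UTY_sh kept as labelled, 50 of 70 splits of the SVE and UTY_sh libraries gave as many as the 6467 genes, with up to 7820 and at least 5885, so chance cannot be excluded for the part that the SVE and UTY_sh libraries play in it. Both sides were also split, in 100 ways with the real one. Besides the real one, 2 kept mNKX3.1 and mNKX3.1+UTY_sh apart and gave 6432 to 6889 genes. Those that mixed these 2 groups gave at most 0 genes in limma. Mixing puts their difference into the spread, which lowers the calls, so the mixed splits decide nothing. With both groups as labelled, the count depended little on how the SVE and UTY_sh libraries were divided.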
